A study of Mus musculus and Rattus norvegicus with 2 samples.

How the data were processed

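Small RNA was sequenced from purified sperm of the caput epididymis, the head of the duct in which sperm mature after leaving the testis. There was 1 mouse library, from C57BL/6 animals aged 2 months, and 1 rat library, from young adult Sprague Dawley rats of 450 g. Per the labels' protocols, RNA was isolated with Trizol, the fraction of 18 to 45 nt was selected, and Illumina libraries were built from it. The submitters' processing notes name Bowtie 0.12.7 and the genome builds mm9 and rn5, with no role or order. Adapter trimming, quality filters and the total number of reads sequenced are not given in the sources used here.

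The deposited tables hold whole, unnormalised read counts per distinct sequence, per the file headers. Each sequence carries a single matched entry from miRBase, Rfam or GenBank, or a piRNA record, with at most 2 mismatches. Each sequence therefore counted in a single class. Sequences on the minus strand were printed as the reverse complement of the read: 78 mouse and 84 rat sequences occurred in duplicate as printed, and 0 in each library after these were turned. A closing line of the mouse table held only the sum of its counts and was left out. Sequence numbers ran to 2253908 in mouse and 1269370 in rat in order of falling count. Of these numbers, 40.6% were listed in mouse and 51.3% in rat, and the rest were not analysed here. Because the numbering follows the counts, the listed reads were bounded at 46.6% to 64.2% of all numbered reads in mouse and at 72.7% to 80.2% in rat. Shares below are of listed reads, and a low or absent value for an RNA can also mean that no entry for it was matched.

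Classes were taken from the entry: Rfam family names were sorted into tRNA, rRNA, snoRNA (with small Cajal body RNAs), snRNA, miRNA and other Rfam RNA, GenBank records by the type printed with them, and miRBase and piRNA records as such. A regrouping by sequence content, chosen after the data were seen, moved into tRNA each read of which at least a share of 0.3 of its 14-nt words occurred in the tRNA reference fragments. It moved reads into rRNA by 18-nt words from abundant reads of the larger rRNA entries, those with 1% or more of rRNA reads. The Rfam tRNA entries do not name an anticodon, so reads were assigned to tRNA families by their 14-nt words in reference fragments written after the data were seen. Valine CAC and AAC share their 5′ part and were kept together. A read was called a 5′-end fragment when its first 14 bases matched the start of a reference with at most 1 mismatch.

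miRNAs were compared by name without the species prefix, as reads per 1000000 listed reads (rpm), with a pseudocount of 0.5 read and a minimum of 100 reads over both libraries. A name without an arm, such as miR-182 in rat, was paired with the more abundant arm of that name left unmatched in the other library. Only miRNAs with reads in both libraries were compared, ranked and placed among random lists, and those with reads in a single library are given apart. Names could hide shared sequences, so a further match used the core sequence, bases 2 to 20 of the most abundant exact read of each name, searched in reads of up to 30 nt of every class. This match was added after the names had been seen to differ. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from 5 bins of mean expression, for lists with at least 3 members compared. These percentiles describe the 2 libraries and are not tests. Mouse reads under mRNA entries were counted for marker genes when an 18-nt word on the sense strand occurred in a GENCODE vM21 transcript of the gene. Coordinates are from GENCODE vM21 on GRCm38, not from the builds named by the submitters. For rat, no genome or annotation was used here. Nuclear tRNA genes and the long rRNA precursor were not matched to a genome here.

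The comparison was mouse against rat, with 1 library per species. No difference therefore has a replicate check, strain, age and species cannot be separated, and no p-value is given. Shares have exact Clopper-Pearson 95% intervals and ratios of shares have exact conditional binomial 95% intervals, printed in parentheses. These cover counting error only, since the reads are PCR products without molecular identifiers. The libraries held 11760708 mouse and 14652889 rat listed reads, so an interval on a class share spans less than 1 percentage point. A count of 0 is taken as compatible with up to 3 counts.

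Before the data were examined, the miRNA lists, the list of sperm tRNA families and the rule for naming RNAs were fixed. The rule named every class with at least 0.1% of reads in either library and the 10 most abundant miRNAs and tRNA families of each library. It also named the 10 highest and 10 lowest miRNAs by log2 ratio, the 3 highest and 3 lowest tRNA families with at least 1000 reads over both libraries, every named rRNA and the 3 most abundant sequences of each library. For the classes with at least 1% of reads, a few of the leading sequences are given. Any other RNA named was chosen after its values were seen. The marker gene lists for mouse mRNA reads were written after the data were seen.

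The ratio calculation was tested on simulated data made from the 86 compared miRNAs, with 40 of them changed 2-fold or 4-fold. At either size, 100% of the changed miRNAs came out within 0.5 on the log2 scale, 96.5% of the intervals held the true ratio, and 0 unchanged miRNAs passed a 2-fold difference. Counts were drawn with counting error alone at the mean rate of both libraries. The simulation therefore does not cover miRNAs with very few reads in a single library. The tRNA family assignment was right for 97.0% of 1650 simulated reads. These were cut from the reference fragments themselves with at most 1 substitution, so they check the assignment step and not whether the references suit the real reads. Alternatives covered other denominators, lengths, distinct sequences in place of reads, removal of dominant sequences, thinning, other scalings and minimums of miRNAs, and matching by sequence, and their effect is given in the closing section. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.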

Results

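Small RNAs of caput epididymal sperm were profiled in 1 mouse and 1 rat library. The mouse library held 11760708 listed reads in 914516 distinct sequences, and the rat library held 14652889 listed reads in 650877. Listed sequences were 18 to 96 nt long. The labels frame the series as a description of sperm small RNAs in both species, so each comparison below asks how a class or an RNA differed between the mouse and the rat library. Values are log2 ratios of rat over mouse unless stated otherwise.

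Transfer RNA fragments were the largest class of the rat library, whereas small nucleolar RNA (snoRNA), which guides the chemical modification of rRNA, was the largest class of the mouse library. tRNA entries took 55.5% of rat reads (55.5 to 55.6) and 25.7% of mouse reads (25.7 to 25.8), a log2 ratio of 1.11 (1.11 to 1.11). snoRNA entries took 37.3% of mouse reads (37.3 to 37.3) and 0.432% of rat reads (0.429 to 0.436), a log2 ratio of -6.43 (-6.44 to -6.42). rRNA entries were 1.99-fold higher in rat, at 16.6% against 8.31%. piRNA entries, named for the short RNAs that silence transposons in the germ line, were 6.28-fold higher in rat, at 4.13% against 0.659%. miRNA entries were 2.73-fold higher in mouse, at 6.06% against 2.22%. With the miR-10 family left out of the class and the total, the log2 ratio was 0.14 (0.13 to 0.15). SNORD58, the leading mouse snoRNA, stayed in the mouse total there. Leaving out SNORD58 alone moved the miRNA ratio from -1.45 to -2.05, a larger shift than 0.14. The higher share in rat without miR-10 therefore rests on SNORD58 in the mouse total, and the ratio without both was not calculated. mRNA entries did not differ detectably at this depth, with 17.9% in both libraries and a log2 ratio of -0.00 (-0.00 to 0.00). The small classes were mitochondrial RNA with 0.737% in mouse and 0.406% in rat, snRNA with 0.534% and 0.624%, other Rfam RNA with 0.398% and 0.498%, and entries of unknown type with 2.32% and 1.68%. The most abundant sequence, a snoRNA in mouse and a Gly-GCC fragment in rat, weighs on every share, and with it left out of each library the tRNA ratio was 0.22 and the rRNA ratio 0.79. Among distinct sequences, the miRNA class had a higher share in rat, with a ratio of 0.77.

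The class of an entry did not always match the sequence of its reads. In rat, 59.6% of mRNA reads carried rRNA sequence, 73.2% of piRNA reads carried tRNA sequence, and 81.5% of unknown reads carried tRNA sequence. In mouse, 60.3% of mitochondrial reads carried rRNA sequence, 34.2% of piRNA reads carried tRNA sequence and 13.9% of mRNA reads carried rRNA sequence. With these reads regrouped, tRNA reached 60.6% in rat and 25.9% in mouse, and rRNA reached 27.4% and 11.5%. The mRNA share fell to 6.60% in rat and 15.4% in mouse, so that mRNA was 2.34-fold higher in mouse. The piRNA share fell to 0.938% in rat and 0.224% in mouse, a ratio of 2.07 (2.05 to 2.09). Mitochondrial RNA turned to a higher share in rat, 0.406% against 0.293%. tRNA, rRNA and piRNA kept their direction under this regrouping, which by construction moved no snoRNA, snRNA, miRNA or other Rfam reads.

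**Figure D1:**
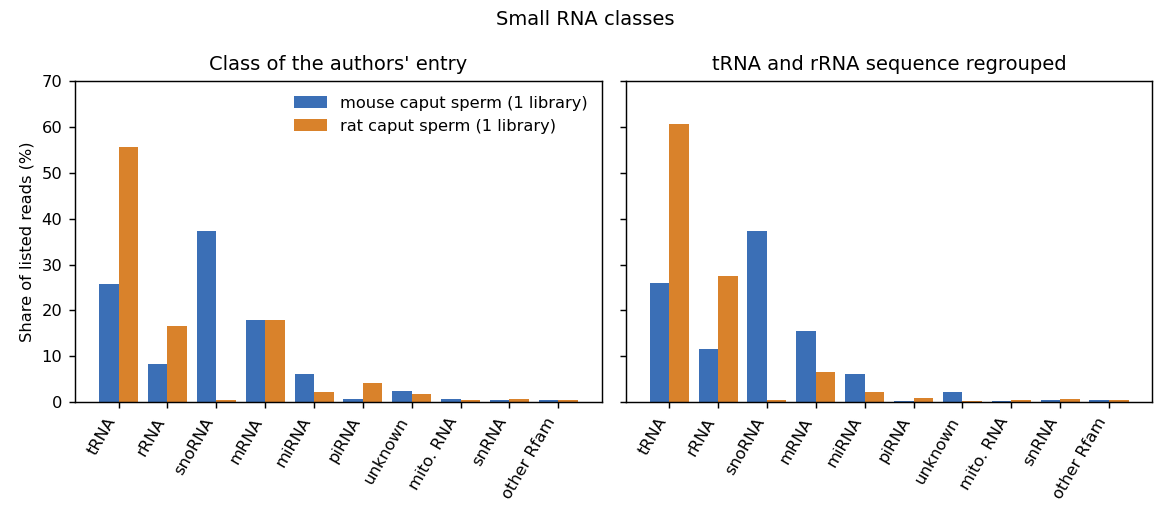
Share of listed reads (percent, from 0) in each small RNA class for the mouse library (blue) and the rat library (orange), with the class of the authors' entry on the left and tRNA and rRNA sequence regrouped on the right. snoRNA stood at 37.3% in mouse and 0.432% in rat, and tRNA reached 60.6% of rat reads after regrouping.

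A single snoRNA made up most of the mouse class. SNORD58, a C/D box snoRNA family, held 4021449 mouse reads, which was 34.2% of the library and 91.6% of its snoRNA reads. No rat read was listed under it. Its leading sequence, the 40-nt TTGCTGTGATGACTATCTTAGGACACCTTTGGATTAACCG, was the most abundant of the mouse library with 3708397 reads (31.5%) and matched bases 1 to 40 of the 65-nt snoRNA Gm26202 without a mismatch. That gene lies on chromosome 18, bases 75001880 to 75001944 of the plus strand in GRCm38, within the bounds of Rpl17. A 39-nt form lacking the first base followed with 192797 reads. The other snoRNA reads were 3.13% of the mouse library, and with SNORD58 left out of the class and the total the log2 ratio was still -3.46 (-3.47 to -3.45). Of 40 mouse snoRNA families with at least 1000 reads, 19 (47.5%) had no rat read listed. The 99 families listed in both libraries by construction leave out families with no rat read. They took 0.880% of all listed mouse and 0.373% of all listed rat reads, a ratio of -1.24 (-1.25 to -1.22). SNORD58 stayed in the mouse total there, unlike in the ratio of -3.46.

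The length profiles followed the leading RNA of each library. The modal length was 40 nt in mouse and 30 nt in rat, and among mouse reads outside snoRNA it was 32 nt. Reads of 26 to 31 nt were 56.3% of rat and 18.7% of mouse reads, a ratio of 1.59 (1.59 to 1.59). Reads of 39 to 41 nt were 36.01% of mouse and 5.32% of rat reads. Reads of 21 to 23 nt, the length of miRNAs, were 9.43% in mouse and 6.18% in rat, and those of 32 to 36 nt were 17.9% and 16.9%. The modal length of miRNA reads was 22 nt in both libraries, and that of tRNA reads was 32 nt in mouse and 30 nt in rat. Among distinct sequences the direction for 21 to 23 nt turned, with a ratio of 0.51.

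**Figure D2:**
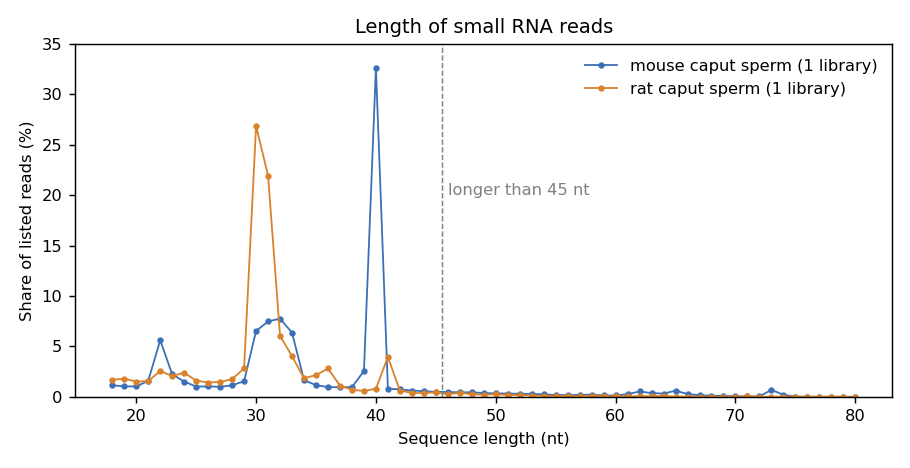
Share of listed reads (percent) at each sequence length in nt, up to 80 nt, for the mouse library (blue) and the rat library (orange), with a dashed line above 45 nt. The mouse library peaked at 40 nt and the rat library at 30 nt, and 7.94% of mouse and 2.74% of rat reads were longer than 45 nt.

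Fragments from the 5′ end of tRNA-Gly-GCC led the tRNA reads of both libraries. Gly-GCC made up 74.0% of rat (74.0 to 74.0) and 60.1% of mouse tRNA reads (60.02 to 60.13), and its leading forms differed in length. The 30-nt GCATTGGTGGTTCAGTGGTAGAATTCTCGC was the most abundant rat sequence with 3086779 reads (21.1% of the library) and had 426480 reads in mouse. The 31-nt form, extended by C, had 2086973 rat and 461549 mouse reads. The 32-nt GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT had 508911 mouse and 387063 rat reads. tRNA-Val-CAC/AAC was the next family in mouse, with 20.5% of tRNA reads against 5.10% in rat, and rested mostly on the 33-nt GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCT with 509872 mouse and 315375 rat reads. Glu-CTC was 12.7% in rat and 9.64% in mouse. His-GTG was 6.35% in mouse and 1.95% in rat.

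Ser followed in rat with 2.59% of tRNA reads against 0.00400% in mouse, and Ala with 0.920% against 0.0122%. Lys-CTT was 1.57% of mouse and 0.471% of rat tRNA reads, and Asp-GTC was 0.507% and 0.0974%. Lys-TTT was 0.150% and 0.622%, Gly-TCC 0.0934% and 0.316%, the selenocysteine tRNA 0.0653% and 0.182%, Leu 0.0438% and 0.170%, and Gln 0.0344% and 0.236%. Under tRNA entries, the highest ratios were those of Ser at 9.34 (9.08 to 9.61), Ala at 6.24 (6.09 to 6.39) and Gln at 2.78 (2.69 to 2.87). The lowest were those of Asp-GTC at -2.38 (-2.42 to -2.34), Val-CAC/AAC at -2.01 (-2.01 to -2.00) and Lys-CTT at -1.73 (-1.75 to -1.72). Ser rested on 121 mouse reads against 210556 in rat, and Ala on 368 against 74886. The families of the list known from sperm, Gly-GCC, Gly-CCC, Glu-CTC, Val-CAC/AAC, Lys-CTT, His-GTG and Asp-GTC, summed to 98.6% of mouse and 94.3% of rat tRNA reads. Under tRNA entries no read was assigned to Gly-CCC, and reads of a form that shares its 5′ part with Gly-GCC count under Gly-GCC. No entry named a mitochondrial tRNA.

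Between 90.4% and 99.2% of the reads of Gly-GCC, Glu-CTC and Val-CAC/AAC began at the 5′ end in either library. Reads that crossed the anticodon and could tell Gly-GCC from Gly-CCC were 364 against 2 in mouse and 15223 against 297 in rat, only 0.0201% and 0.247% of the family, so the 5′ fragments themselves were assigned by family. The most abundant tRNA sequence held 16.8% of mouse tRNA reads, a Val fragment, and 37.9% of rat tRNA reads, a Gly-GCC fragment, and with both left out the ratio of Gly-GCC was by construction lower, at -0.31, and that of Val-CAC/AAC higher, at 0.91. With tRNA reads of every class counted, the ratio of His-GTG moved from -1.70 to -0.33, as 200273 rat reads of unknown type and 85871 under piRNA entries were His-GTG fragments. Those of unknown type were led by the 32-nt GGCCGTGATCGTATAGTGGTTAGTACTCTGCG with 81951 reads. The order of the families changed as well. The highest ratios were then those of Ser at 6.81 (6.70 to 6.93), Ala at 6.11 (5.96 to 6.26) and the initiator Met-CAT at 5.40, which had 937 mouse and 115470 rat reads against 903 and 8091 under tRNA entries. Glu-TTC followed at 4.59, with 445 and 31224 reads, and Gln stood at 2.68. The lowest were those of Val-CAC/AAC at -2.10, Lys-CTT at -1.53 and Gly-CCC at -1.14, with 4594 and 6063 reads, whereas Asp-GTC stood at -0.04 (-0.07 to -0.01).

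**Figure D3:**
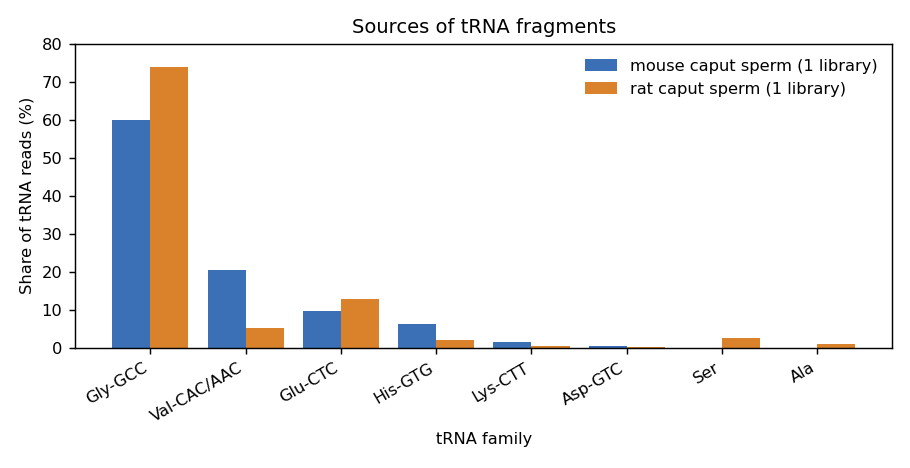
Share of tRNA reads (percent, from 0) by tRNA family in the mouse library (blue) and the rat library (orange), with the families set by sequence. Gly-GCC led both libraries at 60.1% in mouse and 74.0% in rat, and Val-CAC/AAC stood at 20.5% in mouse and 5.10% in rat.

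The miR-10 family dominated the miRNAs of both libraries and was more abundant in mouse, whereas the miR-34 and miR-449 families, which are expressed in male germ cells and ciliated epithelium, were far more abundant in rat. By core sequence, miR-10a and miR-10b together were 83.2% of mouse (83.1 to 83.3) and 41.4% of rat miRNA reads (41.2 to 41.6). miR-10b-5p had 37081 rpm (reads per 1000000 listed reads) in mouse and 6329 in rat, a ratio of -2.55, and miR-10a-5p had 11358 and 1915, a ratio of -2.57. Mir10b lies on mouse chromosome 2, bases 74726070 to 74726137, within the bounds of Hoxd3 and Hoxd4, and Mir10a on chromosome 11, bases 96317165 to 96317274. By name, miR-34c-5p had 502.6 rpm in rat and 4.25 in mouse, a ratio of 6.87 (6.48 to 7.32). The other arm, miR-34c-3p, differed far less, with 11.3 rpm in rat and 5.95 in mouse. Its ratio was 0.92 (0.52 to 1.35) by name and 1.05 by core sequence. miR-449a-5p had 209 and 0.510, a ratio of 8.56 (7.56 to 10.13) that rested on 6 mouse reads. Mir34c lies on chromosome 9, bases 51103034 to 51103110, and Mir449a on chromosome 13, bases 113037534 to 113037624, within the bounds of Cdc20b.

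Matched by name, 86 miRNAs with reads in both libraries passed the minimum, of which 44 were at least 2-fold higher and 13 at least 2-fold lower in rat, with a median log2 ratio of 1.01. Scaled to miRNA reads, the median was 2.53 and the split was 71 against 5, so that 93.4% of the differences were higher in rat, compared with 77.2% in rpm. Matched by core sequence, 102 miRNAs gave 46 higher and 15 lower, with a median of 0.84. Left out of these counts were miRNAs over the minimum with reads in a single library, by name 13 in mouse and 13 in rat, and by core sequence 2 in mouse, miR-3107-5p and miR-3535, and 6 in rat. The miR-10 family set much of the total: without it, miRNAs came to 9764 rpm in mouse and 11657 in rat. SNORD58, with 34.2% of listed mouse reads and 0 rat reads, is part of the mouse total and raises every rpm ratio alike.

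After miR-449a-5p and miR-34c-5p, the highest ratios by name among miRNAs with reads in both libraries were those of miR-101b-3p, miR-34b-3p, miR-34b-5p, miR-150-5p, miR-148b-3p, miR-199a-3p, miR-741-3p and miR-16-5p, from 5.99 down to 4.23. The lowest were those of miR-10b-5p, miR-200c-3p, miR-183-5p, miR-99b-5p, miR-127-3p, let-7b-5p, miR-871-3p, miR-100-5p, let-7a-5p and let-7d-5p, from -13.23 up to -1.68. By name, let-7g-5p with 663 mouse reads and miR-470-5p with 107 had no rat read, and by core sequence they had 290 rat reads and 1. Names misplaced others as well. The rat file listed 49 reads under miR-10b-5p, because most rat reads with the miR-10b core were listed under miR-10a-5p, and the ratio was -2.55 by core against -13.23 by name. The 23808 rat reads listed under miR-148b-3p belonged mostly to miR-148a-3p, which by core sequence had 1726 rpm in rat and 1100 in mouse. By core sequence, miR-200c-3p had a ratio of -1.75 against -4.84 by name, miR-871-3p -0.91 against -2.27, miR-101b-3p 3.62 against 5.99, and the core that miR-199a-3p shares with miR-199b-3p 1.31 against 4.60. After miR-449a-5p and miR-34c-5p, the highest ratios by core sequence among miRNAs with reads in both libraries were those of miR-881-3p at 6.09 (3.59 by name), miR-34b-5p, miR-34b-3p, miR-471-5p, miR-451a, miR-743b-5p, miR-741-3p and miR-150-5p, down to 4.55. With no mouse read, miR-3585-5p had 842 rat reads by core sequence, miR-743b-3p 539, miR-871-5p 341, miR-28-3p 278, miR-743a-3p 218 and miR-463-5p 128. miR-183-5p, encoded on mouse chromosome 6 at bases 30169668 to 30169737, was lower in rat both by name (-4.20) and by core sequence (-3.66).

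By name, miR-10b-5p and miR-10a-5p were followed in mouse by miR-191-5p, miR-143-3p, miR-148a-3p, let-7c-5p, miR-183-5p, miR-99b-5p, miR-182-5p and let-7a-5p, from 909 down to 261 rpm. In rat, miR-10a-5p was followed by miR-143-3p with 1844 rpm, miR-148b-3p, miR-191a-5p, miR-34c-5p, miR-30a-5p, miR-22-3p, miR-182, miR-26a-5p and miR-16-5p with 259. The most abundant miRNA sequence of both libraries was TACCCTGTAGAACCGAATTTGT, with 342622 mouse and 64840 rat reads.

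Among the fixed lists, miR-34 and miR-449 members summed to 14.2 rpm in mouse and 900.3 in rat, a ratio of 5.99 (5.77 to 6.22). Of the 5 members compared, 4 were at least 2-fold higher, and miR-34c-3p stood at 0.92. The list's median lay 4.68 above that of all compared miRNAs, at percentile 100 of the random lists. The X-linked testis cluster had a ratio of 2.67 (2.49 to 2.86), with 2 of the 3 members compared higher, miR-871-3p lower and a median at percentile 74.9. Over the minimum in a single library by name were miR-743b-3p, miR-871-5p, miR-743a-3p and miR-201-5p in rat and miR-470-5p in mouse. By core sequence it had 3.42 (3.24 to 3.59) and percentile 99.8, with 4 of the 6 members compared higher and miR-470-5p lower, at 111 mouse reads and 1 rat read, and with 4 further members over the minimum in rat alone. The miR-17-92 cluster and its paralogs had a ratio of 2.76 (2.60 to 2.93), with 4 of 4 members higher, among them miR-25-3p with 1514 rat and 121 mouse reads, and a median at percentile 84.9. By core sequence the ratio was 1.60, with 4 of 5 members higher and miR-92a-3p at 0.016. The let-7 family, which promotes differentiation, had a ratio of -1.26 (-1.30 to -1.22) with 5 of 8 members at least 2-fold lower and a median at percentile 0.45. Scaled to miRNA reads, which shifts every miRNA alike, its ratio was 0.25, and by core sequence without miR-10 it was -1.53. Relative to all miRNAs its median lay at -2.25. The list of miR-10, miR-99, miR-100 and miR-125 had -2.52 (-2.53 to -2.52), and its median lay at -1.50 relative to all miRNAs, at percentile 3.35. The miR-30 family had a ratio of 1.11 (1.05 to 1.16), and its median stood at -0.01 relative to all miRNAs, at percentile 60.4. The paternal stress set, miRNAs known from sperm of stressed males, had 0.64 (0.60 to 0.69), and its median stood at -0.16 relative to all miRNAs, at percentile 59.6.

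Lists of other cell types gave the following values. Epithelial miRNAs summed to 1240.0 rpm in mouse and 800.1 in rat, a ratio of -0.63 (-0.67 to -0.60), which was 0.89 when scaled to miRNA reads and -1.22 by core sequence without miR-10, and their median stood at -0.14 relative to all miRNAs. Of 9 members, 4 were at least 2-fold higher and 2 lower in rat. Leukocyte miRNAs had 4.51 and 26.4 rpm, a ratio of 2.55 (2.13 to 2.99), with a median at percentile 88.6. Muscle miRNAs, nearly all miR-143, had 847 and 1855, a ratio of 1.13 (1.10 to 1.16), and the endothelial miR-126 had 15.7 and 27.0, a ratio of 0.78 (0.52 to 1.04). Its only compared member, miR-126a-5p, stood at -0.18 relative to all miRNAs. The erythroid list had -0.37 (-0.83 to 0.09) by name and 5.20 (4.35 to 6.21) by core sequence, where it rested on miR-451a with 11 mouse and 498 rat reads. The core value leaves out miR-486-5p, whose core was counted under the name miR-3107-5p with 2386 mouse reads and no rat read, and with this core included the ratio was -2.57 (-2.71 to -2.43). The list of liver and neuron miRNAs had 28 mouse reads and 1 rat read by name, a ratio of -5.12 (-10.48 to -2.53), and 21 and 78 reads by core sequence, a ratio of 1.58 (0.87 to 2.35).

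**Figure D4:**
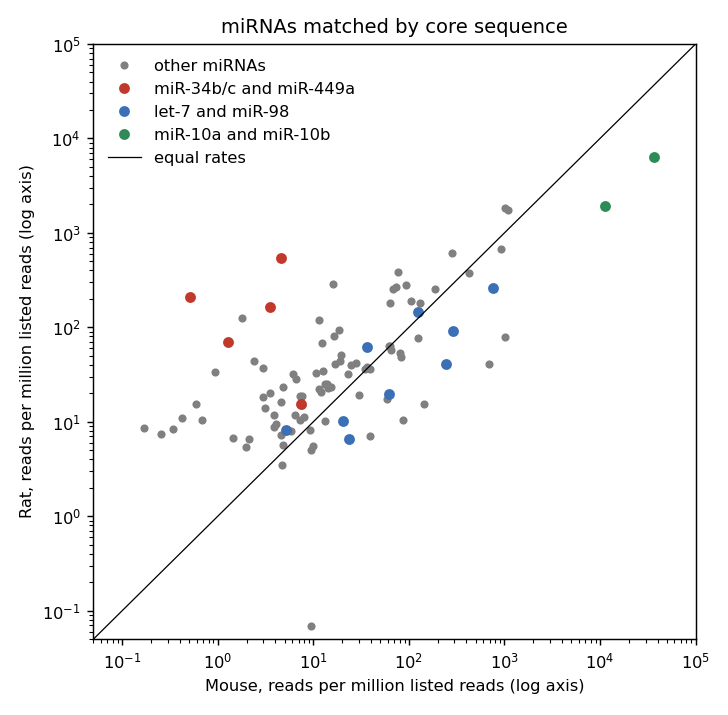
Abundance (rpm) of each miRNA matched by core sequence in mouse (x, log axis) and rat (y, log axis), with miR-34b/c and miR-449a in red, let-7 and miR-98 in blue, miR-10a and miR-10b in green, and a line of equal rates. The miR-34c-5p core had 4.59 rpm in mouse and 547 in rat, and miR-10b-5p had 37081 and 6329. let-7 members lie on both sides of the line, and their summed ratio was 0.25 when scaled to miRNA reads and -1.53 by core sequence without miR-10.

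The 5′ end of 28S rRNA was abundant in rat and unlisted in mouse. Reads holding its start, CGCGACCTCAGATCAGACG, numbered 1199166 in rat, 8.18% of the library, and 0 in mouse, and 1017453 of them were listed under mRNA entries. The 41-nt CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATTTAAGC was the third most abundant rat sequence with 510984 reads. An internal 28S sequence, ACGAGAACTTTGAAGGCCGAAG, was found in 230486 mouse reads (1.96%) and 122270 rat reads (0.834%). Among rRNA entries, 18S was 19.7% of mouse and 5.04% of rat reads, a ratio of -1.96 (-1.97 to -1.95). 5.8S was 0.538% and 2.72%, a ratio of 2.34 (2.30 to 2.38), and 5S was 15.5% and 13.0%, a ratio of -0.26 (-0.27 to -0.25). As for 28S, the 5.8S 5′ end was unlisted in mouse: over all classes, 0 mouse and 75845 rat reads held it, 55941 of the latter under mRNA entries. GenBank rRNA records took 64.3% and 79.3%. As a share of all listed reads, 5S was higher in rat, at 2.15% against 1.29%.

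Reads under piRNA entries were counted for T (U in RNA) at base 1, a mark of piRNAs, and for A at base 10. T at base 1 was found in 33.4% of mouse (33.0 to 33.7) and 15.7% of rat reads (15.6 to 15.8), against 11.4% and 12.5% of tRNA reads and 23.2% and 14.2% of rRNA reads. Among distinct sequences the order was the opposite, 40.1% in mouse and 73.2% in rat. With tRNA and rRNA sequence taken out, 39.02% of the remaining mouse reads and 60.5% of the remaining rat reads began with T. A at base 10 was found in 12.4% of mouse and 10.1% of rat piRNA reads, and in 18.98% and 29.03% of the remaining reads. The remaining reads differed in length, with a mode of 18 nt in mouse and 30 nt in rat. At 26 to 31 nt the libraries were closer: T at base 1 in 58.3% of remaining mouse and 62.6% of remaining rat reads, and A at base 10 in 27.7% and 27.8%. The modal length of piRNA reads was 30 nt in mouse and 31 nt in rat. The most abundant rat piRNA sequence was GCATTTGTGGTTCAGTGGTAGAATTCTCGC with 74591 reads, a Gly-GCC fragment. Beside them, 31.4% of mouse and 8.39% of rat reads of unknown type and 26 to 31 nt began with T.

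Both libraries shared 55911 identical sequences. These carried 41.4% of mouse reads (41.4 to 41.4) and 73.5% of rat reads (73.4 to 73.5), and 58.1% of them had the same class in both files. Shared sequences carried 92.2% of mouse and 96.6% of rat tRNA reads and 97.9% and 88.0% of miRNA reads. They carried 81.3% and 57.1% of rRNA reads, and only 0.791% of mouse and 15.3% of rat snoRNA reads.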

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

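The comparison of the mismatch at base 6 with other bases was chosen only after the result was seen, as was the control at base 5, whereas the search for its paired base was planned before that base was counted. Positions count from 1 at the 5′ end of the fragment, and the reference base is given before the position. Each signal below lies above the limit that a count of 0 allows, in a property that no comparison was about: the deposited mismatches, and lengths beyond the stated fraction. Passing this limit says little, since base 20 of mouse Gly-GCC, with 182 mismatched reads, passes it too. The reads themselves count in the class shares.

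In the mouse library, 17.6% (17.5 to 17.7) of 1792107 Gly-GCC 5′ fragments differed from the reference at base 6, and 97.3% of these were G6T. This share was 342 times the median of the other bases from 2 to 20, which argues against random sequencing error. Another gene copy carrying the change would need its paired A at base 67, and 0 of 732 mouse 3′ fragments had it, an upper bound of 0.503%, below the 1.71% set in advance as excluding such a copy. Whether 3′ fragments sample the copies evenly is unknown, since T5G made up 1.28% of mouse 5′ fragments with its paired C at base 68 in 0 of 732. In rat that C was found in 29.9% of 4060 against 4.60% mismatched at base 5, and whether T5G is encoded was not tested. Another gene copy, a strain variant or a base change at a modified nucleotide may therefore each lie behind G6T. The change was not particular to Gly-GCC. In Glu-CTC, G6T was found in 3.09% of mouse and 4.14% of rat 5′ fragments, beside T5C in 3.02% and 4.04%. Lys-CTT was mismatched at base 6 in 1.99% and 1.21%, whereas Val-CAC/AAC, with C at base 6, was mismatched there in 0.172% of mouse reads. In rat, G6T was found in 2.16% of Gly-GCC 5′ fragments. Its 30-nt and 31-nt forms had 74591 and 50995 rat reads under piRNA entries. The rat Gly-GCC shares are limited by their entry, since 99.99% of rat Gly-GCC reference fragments already used both allowed mismatches against it. Apart from the search for the paired A, no biological explanation was tested.

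In the rat library, 30.5% (30.3 to 30.8) of 106347 fragments of the initiator tRNA-Met-CAT, counted over all classes and with 60936 reads in a single sequence under piRNA entries, differed from the reference at base 9, as G9T in 44.4% of these, G9C in 31.02% and G9A in 24.5%. Reads longer than 45 nt, outside the stated fraction, were 7.94% of the mouse library (7.92 to 7.96) and 2.74% of the rat library (2.73 to 2.75). In mouse, snoRNA entries held 32.5% of these long reads and mRNA entries 33.2%. In rat, mRNA entries held 61.3% and rRNA entries 30.4%.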

How the results depend on the processing

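No paired analysis was possible because there was 1 library per species and no result came from a test. The alternatives without SNORD58, by sequence content, at 18 to 45 nt, without mismatches, with tRNA reads of all classes, by core sequence, without miR-10, per library and with tRNA and rRNA sequence taken out of piRNA were chosen only after the data were seen. All values are log2 ratios of rat over mouse unless stated otherwise. Over 169 alternatives of 29 results, 17 changed sign and were counted as reversed, as given here, 38 stayed within the counting interval or within 1.5 times the count, and the others moved. The 38 include the class ratios after thinning and the classes that regrouping by sequence content left untouched (snoRNA, snRNA, miRNA and other Rfam RNA), which show no stability. A reversal was counted only where the main interval excluded 0, a rule set after the mRNA class was seen to lie at -0.00. Of the moved values, 35 belong to mRNA, the smaller classes and length ranges, and are not all listed. The mRNA class ran from -1.29 at 20 to 35 nt to 0.96 without mismatches, with -0.60 without SNORD58. Class ratios leave out the most abundant sequence of each library, and shares within tRNA and rRNA that of the class itself. Splitting reads between several classes or several tRNAs was not run, since each sequence has a single entry. Where no reason is given, the cause was not tested.

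The tRNA class stayed higher in rat in every alternative run, between 0.036 and 1.22. Its ratio was 1.10 without unknown entries, 0.67 by distinct sequences, 1.10 without single-read sequences, 0.35 at 20 to 35 nt, 0.22 without the most abundant sequence of each library, 0.51 without SNORD58, 1.22 by sequence content, 1.03 at 18 to 45 nt and 0.036 without mismatches. The rRNA class, also higher in rat in every alternative, gave in the same order 0.98, 1.25, 0.99 (within its interval), 0.62, 0.79, 0.39, 1.25, 1.06 and 1.98. The snoRNA class stayed lower in rat, with -6.44 (within its interval) without unknown entries, -0.64 by distinct sequences, -6.55 without single-read sequences, -2.41 at 20 to 35 nt, -3.95 without the most abundant sequence, -3.46 without SNORD58, -6.75 at 18 to 45 nt and -6.00 without mismatches. The miRNA class reversed without miR-10, to 0.14 (0.13 to 0.15), which rests on SNORD58 in the mouse total, and by distinct sequences, to 0.77. It gave -1.46 without unknown entries, -1.47 without single-read sequences, -2.23 at 20 to 35 nt, -1.66 without the most abundant sequence, -2.05 without SNORD58, -1.53 at 18 to 45 nt and -1.23 without mismatches. The piRNA class stayed higher in rat, with 2.07 at 20 to 35 nt, 2.44 without the most abundant sequence, 2.05 without SNORD58, 2.07 by sequence content, 2.57 at 18 to 45 nt and 3.31 without mismatches.

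Smaller classes reversed as follows. snRNA went to -1.16 at 20 to 35 nt and -0.38 without SNORD58, and other Rfam RNA to -0.50 and -0.28. Unknown entries went to 0.070 by distinct sequences, 0.28 at 20 to 35 nt and 0.44 at 18 to 45 nt, and mitochondrial RNA to 0.47 by sequence content. The share of 21 to 23 nt went to 0.51 by distinct sequences. Modal length was 18 nt in both libraries by distinct sequences. Without the most abundant sequence it was 32 nt in mouse and 31 nt in rat.

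Dropping the most abundant tRNA sequence took a Val fragment from mouse and a Gly fragment from rat, which by construction reversed Gly-GCC to -0.31 and Val-CAC/AAC to 0.91, and moved Glu-CTC to 0.82 and His-GTG to -1.28. At 28 to 36 nt, Gly-GCC was 0.37, Glu-CTC 0.47, Val-CAC/AAC -1.96 and His-GTG -1.81. By distinct sequences, Gly-GCC reversed to -1.08, Glu-CTC was 2.13, Val-CAC/AAC -1.81 and His-GTG -1.37. With tRNA reads of all classes these were 0.24, 0.20, -2.10 and -0.33, and the initiator Met-CAT went from 1.74 to 5.40 and Asp-GTC from -2.38 to -0.04. Without mismatches they were -9.11 (reversed), 8.86, -10.74 and -5.63. This left 1739 of 6022370 rat Gly-GCC reads, 2982 of 291707 mouse Glu-CTC reads, and 5095 mouse and 2 rat Val-CAC/AAC reads. Of reads with the reference start, 99.99% in rat Gly-GCC, 99.8% in mouse Val and 97.46% in rat Val use 2 mismatches against their entry, so these values depend on the entries matched.

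miRNAs at least 2-fold higher in rat numbered 71 scaled to miRNA reads, 25 centred on the median and 12 at a minimum of 1000 reads, against 44. Those at least 2-fold lower numbered 5 scaled to miRNA reads and 7 at a minimum of 1000 reads, against 13. Fewer miRNAs are compared at that minimum. All these counts leave out miRNAs with reads in a single library. The erythroid list, 5.20 by core sequence, was -2.57 with the core of miR-486-5p included, an alternative added after the data were seen and kept outside the counts above. Both counts lay within 1.5 times the main ones for a pseudocount of 5, a minimum of 20 reads, 20 to 24 nt, identical sequences, core sequence and miR-10 left out. Without the most abundant rRNA sequence, 5S was -0.31, 18S -2.01 and 5.8S 2.29. By distinct sequences the 5S difference was no longer detectable, at 0.046 (-0.01 to 0.10), with 18S at -1.60 and 5.8S at 1.93, and per listed reads of the library 5S reversed to 0.74, with 18S at -0.97 and 5.8S at 3.33. T at base 1 of piRNA reads was 46.2% in mouse and 14.3% in rat at 26 to 31 nt, 40.1% and 73.2% by distinct sequences, and 39.02% and 60.5% with tRNA and rRNA sequence taken out. Identical sequences with at least 10 reads numbered 28666 and carried 47.6% of mouse and 77.5% of rat reads. With the rat library thinned to the mouse total, identical sequences carried 41.2% of mouse reads. Class ratios stayed within their counting intervals, which random thinning ensures and which says nothing more. Depth limits miRNAs with few reads in either library, such as miR-449a-5p with 6 mouse reads.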

Other observations

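The test of entries missing from the rat set and the test of tRNA and rRNA sequence under piRNA entries were chosen only after the result was seen, as were the mRNA marker lists and the values without SNORD58.

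Mouse reads under mRNA entries included transcripts of the caput epithelium. The 15 genes of that list held 66935 reads, 3.69% (3.66 to 3.72) of mRNA reads outside tRNA and rRNA sequence. They were led by Gpx5, a secreted glutathione peroxidase, with 24221 reads, Adam7, a membrane protein of the epididymis, with 13805, and Spag11b, a defensin-like secreted peptide, with 10651. The counts depend on the matching: only 38.7% of these mRNA reads had a RefSeq entry matched to a gene, and by it these genes had 9940, 8900 and 4072 reads. As shares of the reads matched this way they were 1.41%, 1.27% and 0.580%, against 1.33%, 0.761% and 0.587% of mRNA reads by transcript. Gpx5 lies on chromosome 13, bases 21286429 to 21292731, and Adam7 on chromosome 14, bases 68497336 to 68533741, in GRCm38. A list of 15 spermatid and sperm genes held 659 reads (0.0363%), led by Smcp with 172 and Odf2 with 140. The leukocyte list held 499 reads, the smooth muscle list 771 and the erythroid list 369. Rat mRNA reads were not matched to genes here.

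Other structured RNAs also differed between the libraries. Y RNA, a partner of the Ro protein, had 530 mouse and 2938 rat reads, a log2 ratio of rat over mouse of 2.15 (2.02 to 2.29). The spliceosomal RNA U1 had 7368 and 70296 reads, a ratio of 2.94 (2.90 to 2.97), and U12 had 2.09 and U4 1.77. Lower in rat were U6 at -1.74, U5 at -1.28, U2 at -0.44, U11 at -0.40 and GenBank snRNA records at -3.70. Vault RNA had 354 and 4277, a ratio of 3.28 (3.12 to 3.44). 7SK, which holds back transcription elongation, was lower in rat at -0.73 (-0.76 to -0.70), and the RNA of the signal recognition particle had 0.62 (0.60 to 0.64). With SNORD58 left out of the total, 7SK had -1.33 (-1.37 to -1.30), this RNA 0.015 (-0.01 to 0.04), U1 2.33, vault RNA 2.67 and Y RNA 1.55. U2 then had -1.05, U5 -1.89 and U6 -2.35.

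snoRNA was the largest class in mouse and among the smallest in rat, and SNORD58 held 91.6% of it in mouse, although without this family the log2 ratio of rat over mouse was still -3.46. A general shortening of snoRNAs to about 40 nt in the mouse library is argued against by the other 39 families. In these, a median of 1.76% of reads were 39 to 41 nt long, against 98.3% for SNORD58, with only SNORD97 above 50% (77.3%). This window is that of SNORD58, so shortening to other lengths was not tested and stays open. In the same 39 families a median of 30.2% of reads were 60 nt or longer. A rat entry set without these families cannot be told apart from their absence in rat sperm: 47.5% of the 40 families with at least 1000 mouse reads had no rat read, between the bounds set for either outcome, and the rat entries were not analysed here. A difference between the species, and preferential capture of the 40-nt form in a single library, stay open and untested.

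The piRNA class was larger in rat. Entries holding tRNA or rRNA sequence are argued against as the whole cause, since the log2 ratio of rat over mouse was still 2.07 (2.05 to 2.09) once such reads were moved, although 2 of the most abundant remaining rat sequences, with 8967 and 3493 reads, resembled Gly-GCC fragments. The remaining reads may include true piRNAs: 87.1% (86.6 to 87.6) of their distinct rat sequences of 26 to 31 nt began with T, against 74.2% in mouse. Among distinct rat tRNA sequences of all lengths, 29.99% did. Counted by reads, T opened 62.6% of the remaining rat and 58.3% of the remaining mouse reads of 26 to 31 nt. The remaining sequences were picked by their match to piRNA records, whose own T share was not examined. The T share therefore cannot tell true piRNAs from a trait of the records. Whether the remaining reads came from sperm, from other germ cells or from a larger set of rat piRNA entries stays open, and a species difference was not tested with a single library per species.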
